A study of Mus musculus with 12 samples.

How the data were processed

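Whole spinal cord was taken from 12 mice at 8 weeks of age, 6 wild type (WT) and 6 heterozygous for the P278KY allele of Gars, the gene of glycyl-tRNA synthetase, with 3 females and 3 males of each genotype. Per the labels' protocols, total RNA was isolated with TRIzol and a column kit with DNase treatment, polyadenylated RNA was selected, stranded libraries were made, and reads of 75 bp were taken from both ends of the fragments on a NextSeq 500. The labels give a mixed C57BL/6J and CAST strain background for every mouse. Each library is named here by its group and by the mouse number in its label, and the numbers are not shared between groups.

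Per the submitters' processing notes, reads were aligned with Bowtie2 2.2.0 and quantified with RSEM 1.2.12, and the authors deposited 1 table of genes per mouse. The deposited expected counts, per the file headers, are RSEM's estimates of reads per gene, in which a read that matches several genes is shared among them, so they need not be whole. The deposited TPM values, per the file headers, are scaled by transcript length and by the sum over all genes of a library. The deposited FPKM values, per the file headers, are scaled by gene length and library total and were not used for any test. The genome build and annotation used by the authors are not given in the sources used here. The tables hold 38924 Ensembl genes with a symbol each, and 155 symbols are used by more than 1 gene. Positions were taken from GENCODE M21 (GRCm38) by gene identifier, which matched 37607 of the 38924 genes.

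Expected counts were rounded to whole numbers. Genes were kept by the filterByExpr rule of edgeR over the 4 groups, which left 17980 genes, and libraries were scaled by the trimmed mean of M values. CPM values are counts over 1e6 counts of the library, where the library total is that of the tested genes times its scaling factor. The main test was edgeR's quasi-likelihood F test with robust dispersion, with P values adjusted by the Benjamini-Hochberg method and a threshold of 0.05. The genotype effect and the sex effect came from an additive model of sex and genotype over all 12 mice. The genotype effect within each sex and the interaction of genotype and sex came from a model with 4 group means, in which all groups share 1 estimate of the spread. Fold changes are log2 values fitted with edgeR's default prior count. Their standard errors (SE) are the absolute log2 change over the square root of the F statistic. A prior count of 2 was used for the log2 CPM values of principal components and list means. R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used. No value was taken from a column without a mouse.

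Before the data were examined, 35 gene lists with 761 entries were fixed: ATF4 targets of the integrated stress response, eIF2 kinases and eIF2 factors, cytosolic and mitochondrial tRNA synthetases, endoplasmic reticulum stress, motor neurons, axon injury, interneurons, synapse, microglia and activated microglia, astrocytes and reactive astrocytes, oligodendrocyte myelin, oligodendrocyte precursors, Schwann cells, sensory ganglion neurons, fibroblasts and meninges, endothelium, pericytes and smooth muscle, ependyma, red blood cells, skeletal muscle, cholesterol synthesis, immediate early genes, glucocorticoid response, interferon response, p53 targets, trophic factors with binding partners of mutant synthetase, clock, mitochondrially encoded genes, nuclear oxidative phosphorylation genes, ribosomal proteins, Y-linked genes and X-linked genes that escape inactivation. Each list was tested with camera of limma on voom log2 CPM with a preset correlation between genes of 0.01, with an estimated correlation as the alternative, and adjusted over the 35 lists. For each list the members past the threshold over all genes were counted, and the count adjusted over the list alone was given beside it. Lists of B cell genes and of bone marrow myeloid genes were added after the data had been seen.

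The genes named in the text followed a rule set at the same time. Among genes past the threshold with the same sign in both sexes and a mean of at least 1 CPM, the 10 largest rises and 10 largest falls were named, with the 5 smallest P values in each direction, Gars, and up to 4 members of each list by P value. Within each sex, up to 5 genes in each direction were named by P value, and for the interaction the 3 smallest P values were named as not passing. For the sex effect, Xist, the Y-linked genes and up to 5 autosomal genes in each direction were named. Predicted genes were named when among the top 3 of their direction. Names outside the rule are given as chosen after their values were seen, and not every gene that the rule names is given in the text.

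Alternatives fixed in advance were the size factors of DESeq2, the Wald test of DESeq2, limma voom with sample weights, no filter and a stricter filter (at least 1 CPM in at least 6 libraries), counts without rounding, each mouse left out in turn, a fold change of at least 1.5, a model without sex, the mean of the within-sex contrasts, fits to 1 sex only, Gars' chromosome left out, and limma on log2(TPM + 1). Added after the data had been seen were a term for mice 9 to 12, fits without mice 1 to 4, fits of mice 1 to 8 only, and fits without mice 7, 10 and 11. Called genes within 10 Mb of Gars were compared with the rest of the genome by a one-sided Fisher's exact test, with windows of 5 and 20 Mb and the whole chromosome beside it. The mean CPM of Gars was also compared between genotypes by an exact two-sided permutation test of log2(CPM + 0.5). Principal components were taken from the 500 most variable genes, with 2000 as the alternative.

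The tests were checked on simulated counts drawn from the real means and library sizes. For the genotype effect over both sexes, with 17980 genes tested and 50 changed at each size, 32.0% of genes changed by 1.25-fold, 62.0% of those changed by 1.5-fold, 72.0% of those changed by 2-fold and 92.0% of those changed by 4-fold were recovered, and 7.2% of the calls were false. For the interaction, with 50 genes at each size, 22.0% of differences of 1.5-fold, 58.0% of 2-fold and 76.0% of 4-fold were recovered. Of 100 simulated lists of 30 genes with no shift, 3 had an unadjusted camera P value under 0.05. The simulated genes were drawn independently of each other. This check therefore cannot show how the preset correlation does on lists whose genes vary together.

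The libraries held 26982140 to 39339999 expected counts. Genes with near-identical copies share reads under RSEM, so the values of pseudogenes and of their parent genes are uncertain. In each pair of replicates the counts differed by more than sampling noise, with a chi-square per degree of freedom of at least 10.25, so no library was counted as a duplicate. The labels give each library its own mouse number, and P values then measure the spread between mice.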

Results

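RNA-seq profiles of whole spinal cord were collected from 12 mice in 4 groups of 3, WT females (mice 1, 2 and 10), P278KY females (3, 4 and 9), WT males (5, 11 and 12) and P278KY males (6, 7 and 8). P278KY mice carried 1 mutant copy of Gars, which encodes the enzyme that charges tRNA with glycine and whose dominant mutations cause Charcot-Marie-Tooth neuropathy. The libraries held 26982140 to 39339999 expected counts, and 17980 genes were tested. The stated purpose was to find transcripts that differ between WT and mutant cord in adult mice.

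Markers of tissues next to the cord differed between libraries. Skeletal muscle genes had a mean log2 CPM of 8.67, 6.54, 6.97 and 5.70 in mice 1 to 4, all females, and of 1.93 to 3.83 in the other 8 mice. Markers of sensory ganglion neurons had a mean log2 CPM of 2.81 in P278KY male 7, 2.28 in WT female 10 and 1.99 in WT male 11, against 0.12 to 0.42 in the other 9. Clock genes had a mean log2 CPM of 5.55 to 5.67 in mice 1 to 8 and of 5.37 to 5.49 in mice 9 to 12. The set of mice 9 to 12 was formed after its clock genes were seen to be low, so its clock values restate that and are no separate test. The log2 difference of the set from mice 1 to 8 was -0.78 (SE 0.10) for Dbp, -0.68 (SE 0.09) for Per2 and -0.35 (SE 0.05) for Per3. Mice 9 to 12 are 1 P278KY female, 1 WT female and 2 WT males, so this set was uneven over genotype in males. The first principal component held 25.6% of the variance and set WT female 1 apart, at -60.5.

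Of the tested autosomal genes, 78 were at 5 CPM or more in at least 2 mice and at 0.1 CPM or less in at least 2 others. Pseudogenes made up 61 of them (78.2%), against 2.8% of the other tested autosomal genes (odds ratio 126, Fisher's exact p = 1.26e-77). The long noncoding gene Gm26825 on chromosome 5, chosen after its values were seen, was at 397.9 to 448.7 CPM in 6 mice. It was at 0 to 0.2167 CPM in the rest. The processed pseudogene Gm8355 on chromosome 10, chosen in the same way, was at 122.9 to 152.7 CPM in the same 6 mice. Its values in the rest were 0 to 0.2656 CPM. Whether the reads of either gene come from another copy was not tested. Fgf21 and Gm15710 were the 2 of the 78 genes that were called for genotype. Some of the 78 followed the tissue differences above, such as these, chosen after their values were seen. Scn10a was at 7.21 to 17.65 CPM in mice 7, 10 and 11, with ganglion RNA. Ppp1r3a was at 21.3 and 9.395 CPM in mice 1 and 3, with muscle RNA.

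**Figure D1:**
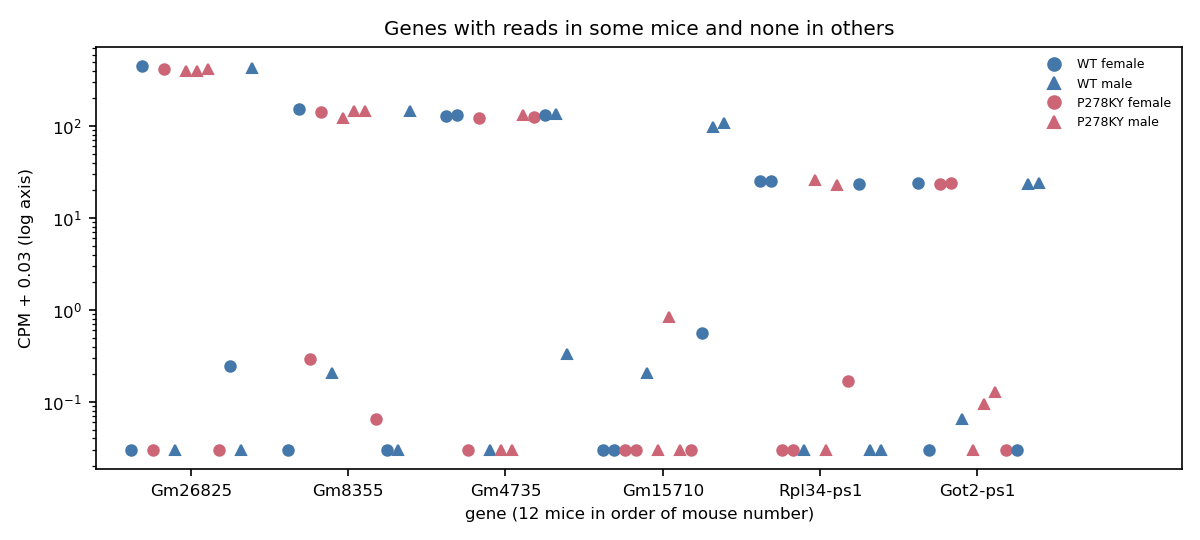
CPM + 0.03 on a log axis (y axis) of 6 genes with reads in some mice and almost none in others, chosen after their values were seen (x axis), 1 point per mouse in order of mouse number, coloured by genotype with sex by shape. Gm26825 lies at 397.9 to 448.7 CPM in 6 mice of both genotypes and near 0 in the others.

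**Figure D2:**
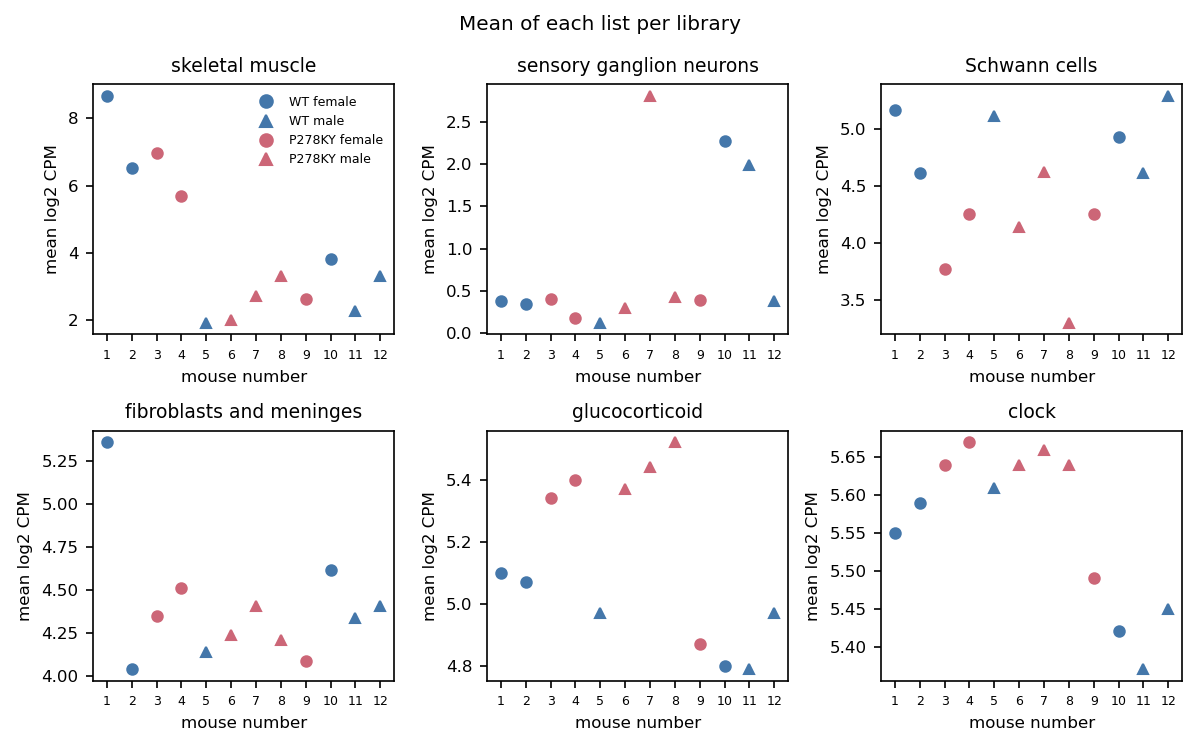
Mean log2 CPM of 6 lists, of skeletal muscle, sensory ganglion neurons, Schwann cells, fibroblasts and meninges, glucocorticoid response and clock (y axis), for each of the 12 mice (x axis), 1 point per mouse, coloured by genotype with sex by shape. Skeletal muscle genes reach 8.67 in WT female 1 and sensory ganglion genes 2.81 in P278KY male 7.

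Transcripts of Gars itself were slightly more abundant in P278KY cord. Gars (ENSMUSG00000029777, chromosome 6, 55038007 to 55079500, plus strand) was at 128.7 ± 6.52 CPM in WT and 140.6 ± 2.95 CPM in P278KY mice (SD, n = 6 each), 1.09-fold higher. All 6 mutants lay above all 6 WT mice, though P278KY female 9 (138 CPM) was barely above WT female 2 (137.8 CPM). WT female 1 was the lowest, at 118.2 CPM. The exact two-sided permutation p was 0.00216, the smallest that 924 permutations give, and took no account of sex. The edgeR log2 change was 0.13 (SE 0.03, adjusted p = 0.046). This call lay at the threshold and was lost when any 1 library other than WT female 1 or WT female 2 was left out, with an adjusted p of up to 0.109 (without P278KY male 7). The counts do not separate the mutant from the WT allele.

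In P278KY cord, 17 of 34 ATF4 targets rose, and 14 of 22 motor neuron genes, 4 of 14 Schwann cell genes and 19 of 23 cholesterol synthesis genes fell. With an estimated correlation the ATF4 list passed (adjusted p = 6.94e-05) and the other 3 lists did not (adjusted p = 0.0605, 0.307 and 0.0605). Fgf21, a hormone released under amino acid and mitochondrial stress, rose from 0.0287 ± 0.0272 to 5.37 ± 0.438 CPM (SD, n = 6), and Chodl, a marker of fast motor neurons, fell from 34.3 ± 5.30 to 7.27 ± 1.31 CPM. Between the genotypes, 956 of 17980 genes passed the threshold, 425 higher and 531 lower in P278KY (44.5% higher). Most changes were small, with a median size of 0.23 on the log2 scale. By size, 132 genes changed by at least 1.5-fold (33 higher, 99 lower) and 57 by at least 2-fold (19 higher, 38 lower). The genotypes did not overlap at all for 244 of the higher and 312 of the lower genes, and for 671 of all tested genes (3.7%), where chance gives 0.22%. On log2(TPM + 1) values 1654 genes passed and the split was 1406 higher and 248 lower (85.0% higher). That setting changed the transformation and the test as well as the scaling, and the cause of the move was not tested. Its median change over all tested genes was 0.062, against -0.003 on the counts, so a list with a small negative median can turn sign there. List medians moved by unlike amounts, from 0.37 to 0.36 for ATF4 targets and from -0.66 to -0.39 for skeletal muscle genes. Of the 956 genes 615 passed there too, all with the same sign. Left-out libraries moved the count to 542 without P278KY male 6, 603 without P278KY female 4, 623 without WT male 11 and 628 without P278KY male 7. Without mice 1 to 4, with the most muscle RNA, it was 557, and without mice 7, 10 and 11, with ganglion RNA, it was 253.

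Targets of the transcription factor ATF4, the effector of the integrated stress response, rose as a group. Of 34 tested targets 17 rose and none fell (26 rose adjusted over the list alone), with a median log2 change of 0.37 (adjusted p = 1.84e-24 with the preset correlation, and adjusted p = 6.94e-05 with an estimated correlation). Fgf21 (chromosome 7, 45613886 to 45615490) had 5 counts in the 6 WT mice and 1024 in the 6 P278KY mice, a ratio of 186 (95% counting interval 79.5 to 575). Adm2, which encodes the peptide intermedin, had 2 counts in WT and 163 in P278KY mice, a ratio of 74.1 (20.2 to 617). The cationic amino acid transporters Slc7a1 (log2 change 0.55, SE 0.05, adjusted p = 3.98e-05) and Slc7a3 (0.76, SE 0.07, adjusted p = 6.27e-05) rose 1.46-fold and 1.69-fold. Sesn2, which restrains growth signalling when amino acids are short, rose 1.38-fold (0.47, SE 0.04, adjusted p = 8.65e-05) and was the 1 riser among 19 tested p53 targets. Outside the naming rule and chosen after their values were seen, Atf4 itself (0.27, SE 0.03), Ddit3 (0.37, SE 0.06), Asns, which makes asparagine (0.28, SE 0.04), and Mthfd2, a mitochondrial folate enzyme (0.39, SE 0.05), also rose.

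Some cytosolic tRNA synthetases also rose. Of 20 tested, 6 rose and none fell (11 rose adjusted over the list alone), with a median log2 change of 0.09 (adjusted p = 1.12e-06). That call was lost with adjusted p = 0.0605 with an estimated correlation. The synthetases for cysteine (Cars, log2 change 0.40, SE 0.04), methionine (Mars, 0.21, SE 0.03), tryptophan (Wars, 0.20, SE 0.03) and leucine (Lars, 0.17, SE 0.03) had the smallest P values (adjusted p = 0.000217, 0.00178, 0.00465 and 0.00801). None of the 17 mitochondrial synthetases and none of the 15 eIF2 kinases and eIF2 factors passed the threshold (list adjusted p = 0.958 and 0.793).

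**Figure D3:**
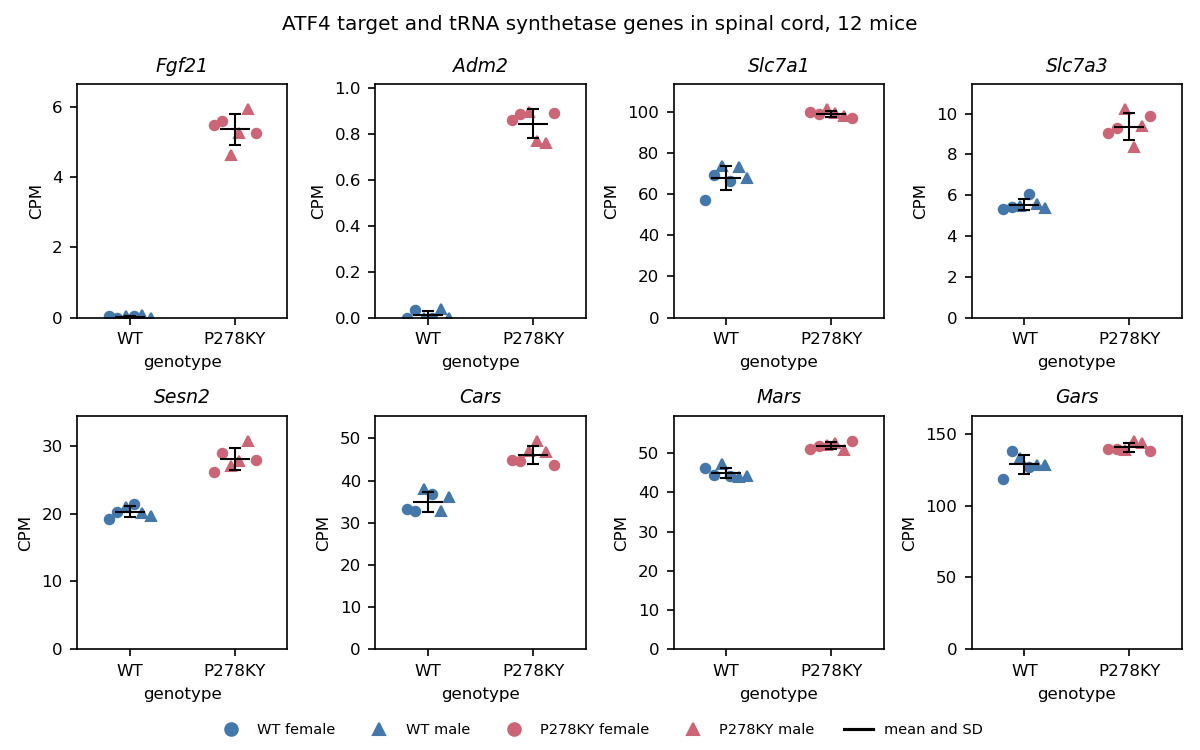
CPM (y axis, from 0) of ATF4 target and tRNA synthetase genes in WT and P278KY mice (x axis), 1 point per mouse with sex by shape, the horizontal line the mean and the bar the SD of 6 mice. Slc7a1 averages 68.0 CPM in WT and 99.2 CPM in P278KY mice, while Gars averages 128.7 and 140.6 CPM.

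Most of the tested motor neuron genes fell. Of 22 tested motor neuron genes 14 fell and none rose (17 fell adjusted over the list alone), with a median log2 change of -0.57 (adjusted p = 8.81e-19). That call was lost with adjusted p = 0.0605 with an estimated correlation. Chodl fell 4.74-fold (log2 change -2.24, SE 0.14, adjusted p = 9.87e-06), and Spp1, the gene of osteopontin, fell 1.65-fold from 114.8 ± 5.67 to 69.7 ± 3.73 CPM (SD, n = 6; -0.72, SE 0.04, adjusted p = 2.47e-06). The calcitonin gene-related peptide genes Calca (-1.97, SE 0.31, adjusted p = 0.00632) and Calcb (-1.50, SE 0.11, adjusted p = 9.87e-06) fell 3.91-fold and 2.82-fold. Both are also made by sensory neurons, and Calca was at 16.9 CPM in P278KY male 7, the library with the most ganglion RNA, against 4.6 to 7.1 CPM in the other 5 mutants. Nefl, the light subunit of neurofilament, fell 1.51-fold from 2098 ± 248 to 1390 ± 29.1 CPM (-0.59, SE 0.07, adjusted p = 0.000368). Among members chosen after their values were seen, Chat, which makes acetylcholine, fell (-0.55, SE 0.12, adjusted p = 0.0241). The motor neuron transcription factors Mnx1 (-0.25, SE 0.16) and Isl1 (-0.06, SE 0.19) and the acetylcholine-degrading enzyme gene Ache (-0.05, SE 0.05) did not pass.

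Interneuron markers did not fall. Of 23 tested, 2 rose and none fell (5 rose adjusted over the list alone), with a median log2 change of 0.08 (adjusted p = 0.00112). That call was lost with adjusted p = 0.297 with an estimated correlation. Tac1, the substance P precursor gene, rose (log2 change 0.39, SE 0.06, adjusted p = 0.00185). Syt1, the calcium sensor of synaptic vesicles, is a member of the synapse list as well, so it does not mark interneurons alone. It also rose (0.16, SE 0.04, adjusted p = 0.0239), a call lost without P278KY male 6 (0.0661) or P278KY male 7 (0.059). Among 30 synapse genes 6 rose and 2 fell (7 and 3 adjusted over the list alone), and the list did not pass (adjusted p = 0.117, 0.0429 without WT female 2, and 0.753 with an estimated correlation). The glutamate receptor subunit gene Gria4 fell (-0.18, SE 0.04), and Gria2 of the same family (0.14, SE 0.03) and the syntaxin gene Stx1a (0.27, SE 0.06) rose. The Gria2 call was lost without P278KY female 4, WT male 11 or WT male 12, with an adjusted p of up to 0.0586. Of 20 axon injury genes, Stmn2, a microtubule regulator of axons, fell (-0.27, SE 0.05). Gap43, a growth cone gene, rose (0.12, SE 0.03, adjusted p = 0.0488), a call lost in 10 of the 12 fits with 1 library left out. In that list 1 rose and 2 fell adjusted over the list alone, and it did not pass (adjusted p = 0.537).

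Some Schwann cell genes fell, with Pmp2 far ahead of the rest, and the amount of spinal root in each sample was not measured. Pmp2 (chromosome 3, 10179851 to 10183929), the fatty acid-binding protein gene of myelin, fell 16.4-fold from 26.0 ± 7.95 to 1.59 ± 0.385 CPM (SD, n = 6; log2 change -4.04, SE 0.24, adjusted p = 1.04e-05). Of 14 Schwann cell genes 4 fell and none rose (7 fell adjusted over the list alone), with a median of -0.72 (adjusted p = 2.74e-06). That call was lost with adjusted p = 0.307 with an estimated correlation. Gldn, which encodes a node of Ranvier adhesion protein, fell by 1.10 on the log2 scale (SE 0.18, adjusted p = 0.00474). Pmp22, a structural gene of peripheral myelin, fell from 592.3 ± 108.8 to 295.7 ± 100.5 CPM (SD, n = 6; adjusted p = 0.0353). The calls of Pmp22 and of the muscle and Schwann cell gene Mlip (-0.94, SE 0.24) were lost in 8 and 10 of the 12 fits with 1 library left out, with an adjusted p of up to 0.0883 and 0.109 (both without P278KY male 6).

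Most cholesterol synthesis genes fell. Of 23 tested, 19 fell and none rose (21 fell adjusted over the list alone), with a median log2 change of -0.29 (adjusted p = 1.08e-20). That call was lost with adjusted p = 0.0605 with an estimated correlation. Dhcr7, which acts late in the pathway, fell (log2 change -0.37, SE 0.06, adjusted p = 0.00361), as did Fdps (-0.21, SE 0.03) and Tm7sf2 (-0.29, SE 0.05). Of 13 mitochondrially encoded genes 2 fell (11 adjusted over the list alone), mt-Nd2 and mt-Nd4l of complex I, calls lost in 8 and 6 of the 12 fits with 1 library left out. The median of that list was -0.19 (adjusted p = 5.28e-08, and adjusted p = 0.307 with an estimated correlation). Nuclear genes of oxidative phosphorylation had a median of -0.07, which was 0.00 on log2(TPM + 1) values, where the median over all tested genes was 0.062. On the counts 4 fell (13 adjusted over the list alone), Ndufa1 (-0.17, SE 0.03), Ndufv3, Ndufb6 and Cox7a2, and the last 3 calls were lost in 6, 7 and 9 of the 12 fits with 1 library left out. The list passed with adjusted p = 4.74e-10, and had adjusted p = 0.297 with an estimated correlation.

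**Figure D4:**
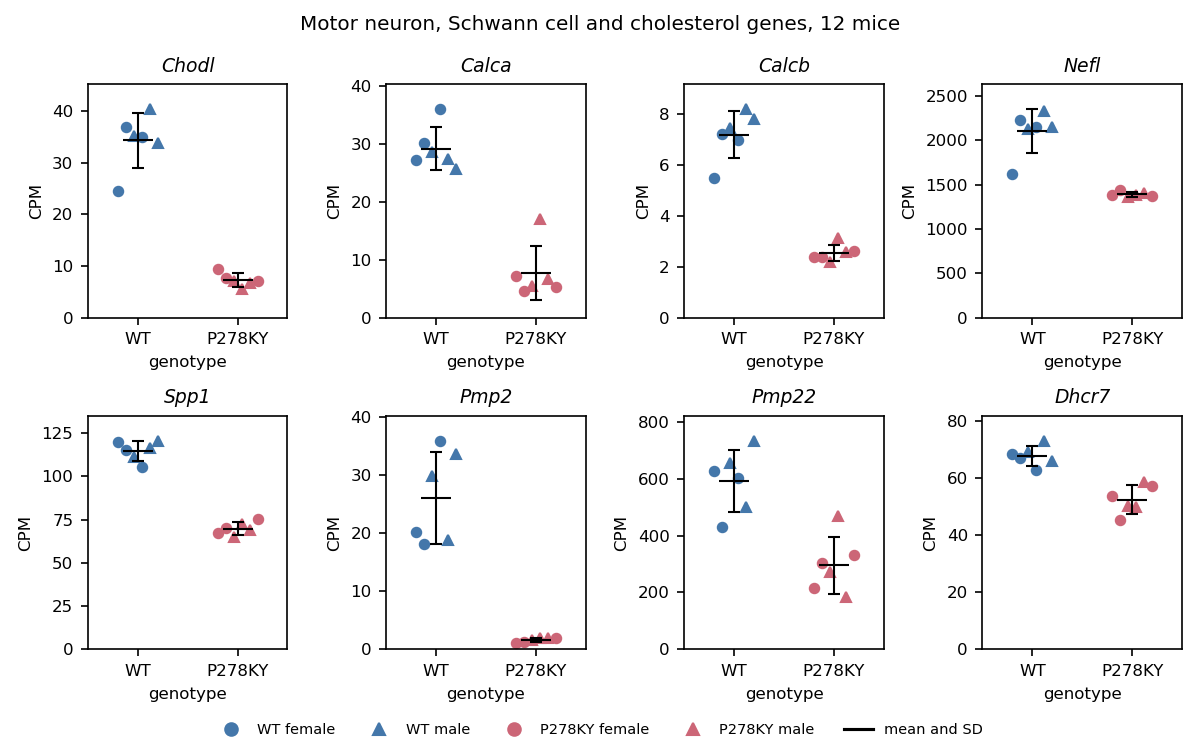
CPM (y axis, from 0) of motor neuron, Schwann cell and cholesterol synthesis genes in WT and P278KY mice (x axis), 1 point per mouse with sex by shape, the horizontal line the mean and the bar the SD of 6 mice. Chodl averages 34.3 CPM in WT and 7.27 CPM in P278KY mice, and Nefl 2098 and 1390 CPM.

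A further 4 lists passed with the preset correlation and none of them with an estimated one. Among 18 glucocorticoid-responsive genes 2 rose (5 rose and 1 fell adjusted over the list alone), Errfi1, a feedback inhibitor of EGF receptors (0.36, SE 0.06), and the hypoxia factor gene Hif3a (0.96, SE 0.20). The median was 0.35 (adjusted p = 8.64e-06, and adjusted p = 0.297 with an estimated correlation). This list had a mean log2 CPM of 5.34 to 5.52 in the 5 P278KY mice numbered 3 to 8 and of 4.97 to 5.10 in the 3 WT mice among mice 1 to 8. In mice 9 to 12 it lay at 4.79 to 4.97, the P278KY female 9 included. The clock list, which parted mice 9 to 12 from the rest, had a median of 0.11 (adjusted p = 0.00724, and adjusted p = 0.307 with an estimated correlation). Its call was also lost without mice 7, 10 and 11 (median 0.05, adjusted p = 0.119) and in females alone (0.104). No clock gene of 18 passed the threshold, also adjusted over the list alone.

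Among 21 endoplasmic reticulum stress genes, Herpud1, of protein degradation, rose (0.26, SE 0.06), and the chaperone genes Pdia3 (-0.12, SE 0.03) and Hsp90b1 (-0.15, SE 0.04) fell (1 rose and 4 fell adjusted over the list alone). The calls of Pdia3 and Hsp90b1 were lost in 8 and 9 of the 12 fits with 1 library left out. The list had a median of -0.08 (adjusted p = 0.015, and adjusted p = 0.476 with an estimated correlation). Its call was lost without P278KY female 3 (adjusted p = 0.0668), WT female 10 (0.0848) or mice 7, 10 and 11 (0.154) and in males alone (0.294). Its median was -0.02 on log2(TPM + 1) values, where the median over all tested genes was 0.062. Among 20 immediate early genes, which neurons switch on when active, Arc (-0.37, SE 0.09) and Egr3 (-0.45, SE 0.12) fell, and each call was lost in 10 of those 12 fits (1 rose and 2 fell adjusted over the list alone). The median was -0.14 (adjusted p = 0.024, and adjusted p = 0.476 with an estimated correlation). This list's call was lost without WT female 1 (0.155), P278KY female 3 (0.0668), P278KY female 9 (0.1) or mice 1 to 4 (0.0789) and in males alone (0.516).

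With all 12 mice, no glial or vascular list other than that of Schwann cells passed the list test, while single members did. Among 15 astrocyte genes, the glutamate transporter gene Slc1a3 rose from 104.8 ± 4.06 to 135.3 ± 4.64 CPM (SD, n = 6; 1.29-fold, adjusted p = 6.4e-05). Agt, the angiotensinogen gene, rose by 0.44 (SE 0.07). Slc7a10, an amino acid transporter gene, fell by 0.18 (SE 0.05), a call lost in 10 of the 12 fits with 1 library left out. In that list 3 rose and 2 fell adjusted over the list alone (list adjusted p = 0.227). No reactive astrocyte gene of 23 passed (adjusted p = 0.793), with a median of -0.07 that was 0.08 on log2(TPM + 1) values and a test direction upward. WT female 1 was at a mean log2 CPM of 4.77 for that list (others of WT 3.93 to 4.23), and the median was 0.10 without it (adjusted p = 0.0979) and 0.08 without mice 1 to 4 (0.305). Of 20 activated microglia genes, the lysosomal protease genes Ctsd (-0.21, SE 0.03) and Ctsz (-0.26, SE 0.05) fell. There 1 rose and 6 fell adjusted over the list alone (median -0.23, list adjusted p = 0.0534, and adjusted p = 0.753 with an estimated correlation). That list passed without WT female 2 (0.00289), WT male 5 (0.0145), P278KY male 6 (0.0254), P278KY male 7 (0.0351), P278KY male 8 (0.044) or WT male 12 (0.0473) and with the term for mice 9 to 12 (0.0485). WT female 1 was at a mean log2 CPM of 4.0 for it (other 11 mice 2.68 to 3.19), and the median was -0.09 without that mouse (0.309) and -0.09 without mice 1 to 4 (0.273). No homeostatic microglia gene of 20 passed, with a median of -0.05 (adjusted p = 0.277) that was 0.01 without WT female 10 (0.963) and 0.08 without mice 7, 10 and 11 (0.176).

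Of 22 oligodendrocyte myelin genes 2 fell (3 adjusted over the list alone), among them Trf, which encodes transferrin (-0.28, SE 0.05). The list had a median of -0.04 (adjusted p = 0.0704, and adjusted p = 0.753 with an estimated correlation). It passed without WT female 1 (0.00096), P278KY female 3 (0.0344), P278KY male 8 (0.0237), P278KY female 9 (0.0225), WT male 12 (0.0479) or mice 1 to 4 (0.0012). In males alone its median was -0.14 (adjusted p = 6.24e-05, and adjusted p = 0.598 with an estimated correlation). No oligodendrocyte precursor gene of 14 passed (1 rose adjusted over the list alone, adjusted p = 0.589). Of 20 fibroblast and meningeal genes, the matrix proteoglycan genes Ogn (-1.17, SE 0.21) and Lum (-0.74, SE 0.19) fell (2 adjusted over the list alone). The Lum call was lost in 8 of the 12 fits with 1 library left out, and the list had a median of -0.22 (adjusted p = 0.0537, and adjusted p = 0.753 with an estimated correlation). It passed without WT female 2 (0.00048), P278KY female 4 (0.0386), WT male 5 (0.0207), P278KY male 6 (0.0349), P278KY male 7 (0.0205), P278KY male 8 (0.044), WT male 11 (0.0447) or mice 7, 10 and 11 (0.0277) and with the term for mice 9 to 12 (0.0252). WT female 1 was at a mean log2 CPM of 5.36 for it (other 11 mice 4.04 to 4.62), and the median was -0.01 without that mouse (0.896), -0.12 without P278KY female 9 (0.222) and -0.11 without mice 1 to 4 (0.136).

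No gene of endothelium passed (16 genes, 1 fell adjusted over the list alone, list adjusted p = 0.0673, and adjusted p = 0.753 with an estimated correlation). The endothelial list passed without WT female 2 (0.000562), P278KY female 4 (0.0446), WT male 12 (0.0479) or mice 1 to 4 (0.000833) and in a test on ranks (0.0425), and its median of -0.16 was -0.04 without WT female 1 (0.303). No gene passed among 12 pericyte and smooth muscle genes (list adjusted p = 0.385), whose median of -0.11 was 0.03 without WT female 1 (0.961), or 18 ependymal genes (0.68). In females alone, the lists of activated microglia, astrocytes, fibroblasts and meninges, and ependyma passed (adjusted p = 0.00259, 0.00717, 0.00115 and 0.0147). With an estimated correlation these 4 had an adjusted p of 0.594, 0.482, 0.594 and 0.603. WT female 1, with lung and muscle RNA, stood apart from WT females 2 and 10 in all 4, at 4.0 against 2.85 and 3.19, 8.11 against 8.24 and 8.27, 5.36 against 4.04 and 4.62, and 1.98 against 1.57 and 1.51 (mean log2 CPM).

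Of 21 trophic factors and binding partners of mutant synthetase, 3 fell and none rose (2 rose and 5 fell adjusted over the list alone), with a median of -0.16 (adjusted p = 0.0537, and adjusted p = 0.247 with an estimated correlation). That list passed without WT female 2 (0.0147), WT male 5 (0.0411), P278KY male 6 (0.049), P278KY male 7 (0.0274), WT male 12 (0.0444) or mice 1 to 4 (0.0375, median -0.04), and its median was -0.09 without WT female 1 (0.0602). In females alone it passed with a median of -0.21 (adjusted p = 0.00717, and adjusted p = 0.103 with an estimated correlation). Cntf, a trophic factor gene of Schwann cells, fell by 0.60 (SE 0.10, adjusted p = 0.00357). The GDNF receptor genes Ret and Gfra1 fell by 0.21 (SE 0.03) and 0.23 (SE 0.04). Of 18 sensory ganglion markers, P2rx3, an ATP-gated channel gene, rose (1.81, SE 0.30, adjusted p = 0.00525) and Calcb fell (1 and 1 adjusted over the list alone). P2rx3 was at 12.8 CPM in P278KY male 7 and at 5.35 to 7.19 CPM in the other 5 mutants. The ganglion list did not pass (adjusted p = 0.978), and its median of -0.23 was 0.02 on log2(TPM + 1) values and -0.72 (without P278KY male 7) to 0.29 (without WT female 10) with 1 mouse left out.

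Of 21 interferon-stimulated genes, Stat2 fell (-0.15, SE 0.04; 1 adjusted over the list alone), a call lost in 11 of the 12 fits with 1 library left out. The median was -0.08 (list adjusted p = 0.274, and adjusted p = 0.825 with an estimated correlation, with 0.044 without P278KY male 8 and 0.0479 without WT male 12). It was 0.03 without WT female 1 (0.859) and 0.02 without mice 1 to 4 (0.93). In females alone the interferon list passed with a median of -0.24 (adjusted p = 0.00317, and adjusted p = 0.603 with an estimated correlation), and in males its median was 0.09. The p53 list did not pass (1 rose adjusted over the list alone, adjusted p = 0.227). No gene passed among 20 skeletal muscle genes (median -0.66, list adjusted p = 0.0537), 8 red blood cell genes (0.265), 4 Y-linked genes (0.552) or 6 X-linked genes that escape inactivation (0.0662; 2 rose adjusted over the list alone). The muscle list passed without P278KY female 3 (0.00194), P278KY female 4 (0.0384), WT male 5 (0.046), P278KY male 6 (0.0493), P278KY male 7 (0.0497), P278KY male 8 (0.0384), WT female 10 (4e-06) or mice 7, 10 and 11 (1.7e-06). It also passed with the term for mice 9 to 12 (0.000146), on ranks (0.00893) and in females alone (0.00729, and 0.651 with an estimated correlation). Its median of -0.66 was 0.14 without WT female 1 (0.961), -0.36 without P278KY female 9 (0.868) and -0.16 without mice 1 to 4 (0.178). The red blood cell list passed without WT female 1 (0.00601), and the X-linked list without WT female 1 (0.0326), P278KY female 4 (0.0498), WT male 5 (0.0474) or P278KY male 6 (0.049). With an estimated correlation and all mice, these 3 lists had an adjusted p of 0.753, 0.753 and 0.297. Likewise no gene of 75 ribosomal protein genes passed, with a median of -0.02 (adjusted p = 0.324).

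**Figure D5:**
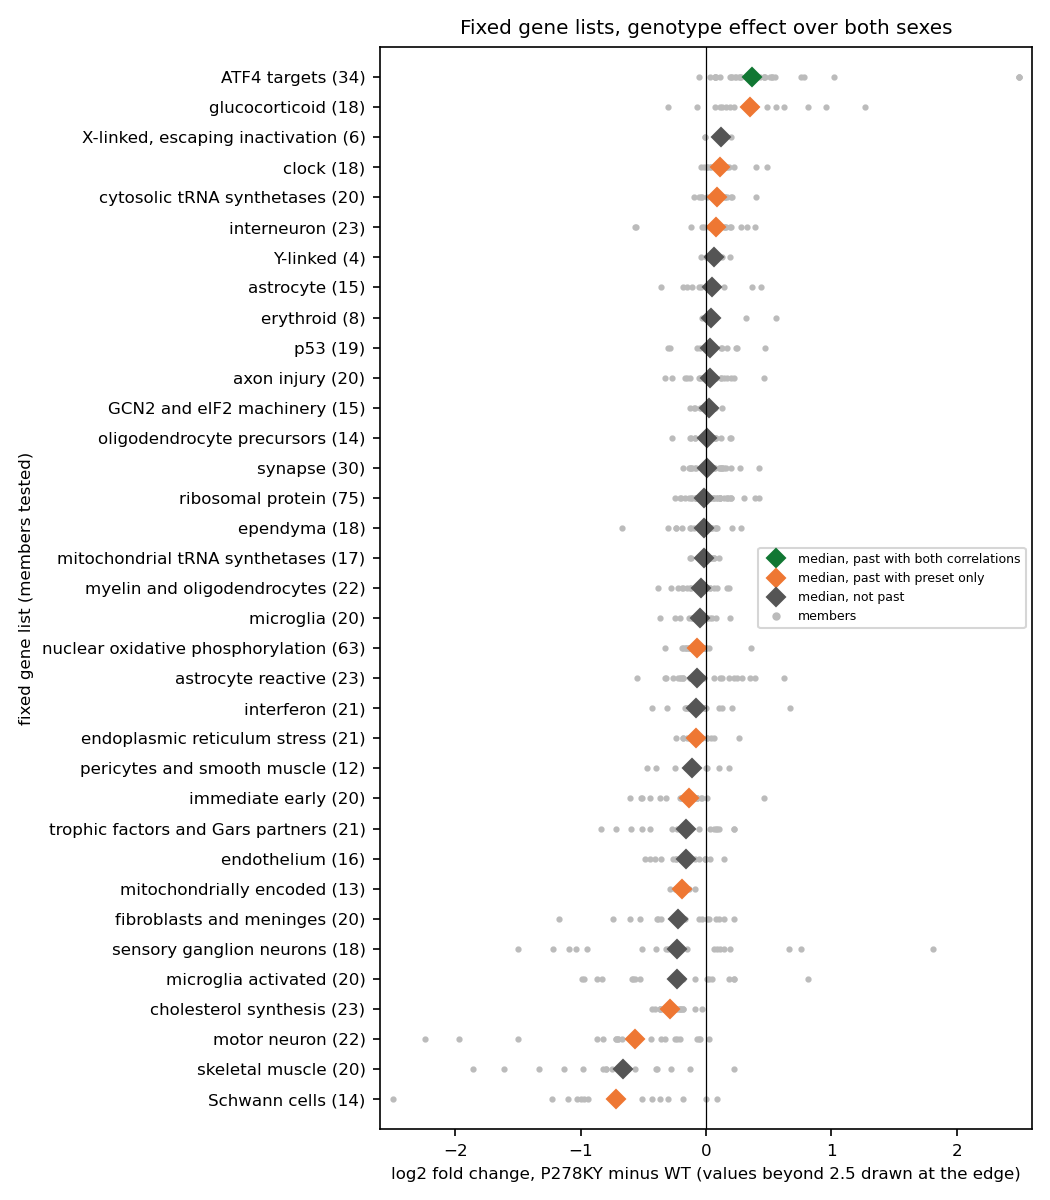
Log2 fold change of P278KY over WT (x axis) for the tested members (grey points) and the median (diamonds) of the 35 fixed lists (y axis), with members beyond 2.5 drawn at the edge. ATF4 targets, at a median of 0.37, passed with both the preset and the estimated correlation, and the medians of motor neuron and Schwann cell genes lie at -0.57 and -0.72.

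Outside the lists, the largest rise at measurable WT expression was that of Cdsn, the gene of a cell adhesion protein of the epidermis, from 0.282 ± 0.0599 to 4.12 ± 0.565 CPM (SD, n = 6; 14.4-fold, log2 change 3.85, SE 0.16, adjusted p = 4.88e-08). Cass4, an adaptor of focal adhesions, rose 2.61-fold, Gabrr2, a GABA receptor subunit, 2.25-fold and Stbd1, which binds glycogen, 2.02-fold (adjusted p = 0.00172, 0.0135 and 0.00443). Galnt15 (0.82, SE 0.13), Mc5r, a melanocortin receptor (0.81, SE 0.18), and the kinase gene Map3k6 (0.80, SE 0.21) followed. The Mc5r call was lost without P278KY male 6 (0.0506) or WT male 11 (0.0601), and that of Map3k6 in 9 of the 12 fits with 1 library left out. Ahnak2, a large scaffold gene, fell 2.29-fold from 240.1 ± 20.1 to 104.8 ± 11.6 CPM (-1.20, SE 0.07, adjusted p = 6.02e-06). Lox, which crosslinks collagen, fell 2.63-fold and Sptbn5, a spectrin gene, 2.68-fold (adjusted p = 3.57e-05 and 0.000178). Lctl (-1.91, SE 0.22), Lect1 (-1.60, SE 0.22), the urotensin gene Uts2b (-1.40, SE 0.16) and the annexin gene Anxa6 (-0.40, SE 0.03) also fell. Of the 956 genes 45 were predicted genes or pseudogenes (24 higher, 21 lower). The predicted gene Gm15710 had the lowest fitted change, but its reads came from WT males 11 and 12 (98.2 and 108.7 CPM) with 0 to 0.804 CPM in the other 10 mice, and its call was lost in 10 of the 12 fits with 1 library left out.

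Called genes were not concentrated around Gars, a check made because the strain background is mixed and a segment around the mutation can carry other alleles. Within 10 Mb of Gars 7 of 120 tested genes were called (5.8%) against 944 of 17577 elsewhere (5.4%; odds ratio 1.09, one-sided Fisher's exact p = 0.468). Windows of 5 and 20 Mb gave an exact p of 0.759 and 0.342, and the whole chromosome gave 55 of 889 (6.2%, exact p = 0.152). Adcyap1r1, a neuropeptide receptor gene 0.4 Mb away, was among the 7, chosen after its value was seen (log2 change 0.16, adjusted p = 0.00277).

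In females, Fgf21 (log2 change 7.72), Cdsn (4.01), Adm2 (5.89), Slc7a1 (0.62) and Papss2, a sulfate donor synthase gene (0.70), rose. Pmp2 (-4.17), Chodl (-1.99), Calcb (-1.41), Ahnak2 (-1.22) and Spp1 (-0.68) fell. The edgeR adjusted p of these genes lay between 7.88e-06 and 0.00212. In all, 103 genes passed in females, 34 higher and 69 lower, with 3 mice against 3. Of the 34 ATF4 targets 8 rose (19 adjusted over the list alone; adjusted p = 0.000471 with an estimated correlation), and of the 22 motor neuron genes 6 fell (14 adjusted over the list alone; adjusted p = 0.103 with an estimated correlation). Of 35 lists 18 passed with the preset correlation and 1, the ATF4 targets, with an estimated one. The count was 32 without P278KY female 4, 43 without WT female 10, 46 without P278KY female 3 or 9 and 66 without WT female 2, P278KY male 6 or WT male 11. It was 156 without WT female 1, the library with the most muscle RNA.

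In males, Fgf21 (log2 change 7.03), Cdsn (3.68), Adm2 (5.65), B4galnt2, a glycosyltransferase gene (3.61), and Galnt15 (1.15) rose. Chodl, Spp1 (-0.76), Calcb (-1.58), Ahnak2 (-1.18) and Fgf1, a growth factor gene of motor neurons (-0.47), fell, with Chodl at 36.44 CPM in WT and 6.438 CPM in P278KY males. The edgeR adjusted p of these genes lay between 1.6e-05 and 0.00289. In all, 279 genes passed, 93 higher and 186 lower, with 3 mice against 3. Of the ATF4 targets 11 rose (23 adjusted over the list alone), of the 22 motor neuron genes 9 fell (16 adjusted over the list alone) and of the 23 cholesterol synthesis genes 10 fell (22 adjusted over the list alone). These 3 lists passed with an estimated correlation (adjusted p = 0.000443, 0.0407 and 0.0407), of 11 with the preset one. WT males 11 and 12 belonged to mice 9 to 12 and no P278KY male did. With a term for those mice the count was 72. Left-out libraries gave 76 without WT male 11, 78 without P278KY male 6, 97 without WT male 12, 146 without WT male 5, 151 without P278KY male 7 and 180 without P278KY male 8. The count was 431 without WT female 1, which shares the estimate of the spread. B4galnt2 had 18 counts in the 6 WT mice of both sexes and 207 in the 6 P278KY mice, a ratio of 10.5 (95% counting interval 6.45 to 18).

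The genotype effect was compared between females and males by the interaction term, and no gene passed. Fgf21 was higher by 7.72 in females and 7.03 in males, and Pmp2 lower with -4.17 and -3.92. By edgeR 0 of 17980 genes passed, 665 had an unadjusted p under 0.05, and DESeq2 and limma voom called 61 and 2 genes. The count was 42 without P278KY male 7, 8 without WT female 1, 8 without WT male 5 and 1 without WT female 10. The genes with the smallest P values were Snx7, a sorting nexin gene (difference of log2 changes, females minus males, -0.89, SE 0.12), Bdh2, a dehydrogenase gene (-1.47, SE 0.20), and Lpar3, a lysophosphatidic acid receptor gene (-3.73, SE 0.51), all on chromosome 3. Of the 103 genes called in females 94 (91.3%) had the same sign in males, and of the 279 called in males 262 (93.9%) had the same sign in females. Of these, 73 were called in both, 72 with the same sign (0.9 expected of independent lists in the same direction). Across all tested genes, which are not independent replicates, the changes in females and males had a Spearman rho of 0.30 and a Pearson r of 0.03. Of 35 lists 16 passed the interaction with the preset correlation and 0 with an estimated one (camera adjusted p of 0.605 or higher), where axon injury genes had the lowest unadjusted p, 0.0288.

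Genes of the sex chromosomes marked the sex of every mouse as given. Xist, the RNA that silences an X chromosome, was at 533.2 ± 100 CPM in WT females and 616.7 ± 38.09 CPM in P278KY females (SD, n = 3) and at 0.3193 ± 0.2646 and 0.3597 ± 0.1454 CPM in WT and P278KY males. Kdm5d, a Y-linked histone demethylase gene, was at 20.25 ± 1.59 and 23.05 ± 1.642 CPM in WT and P278KY males and at 0 in all 6 females, and Uty, Ddx3y and Eif2s3y of the Y chromosome also passed (edgeR adjusted p = 1.12e-09, 3.75e-13 and 3.35e-13). All 4 Y-linked genes were lower and all 6 X-linked escape genes higher in females (4 and 6 adjusted over the list alone; both lists adjusted p = 3.62e-05 with an estimated correlation). In all, 16 genes passed, 9 higher and 7 lower in females. Among autosomal genes, Penk, the enkephalin precursor gene (log2 change -0.38, adjusted p = 9.41e-05), and Slc15a2, a peptide transporter gene (-0.69, adjusted p = 0.0103), were lower in females. Fam129c (0.59, adjusted p = 0.0158) and Pou2af1, a B cell coactivator gene (1.32, adjusted p = 0.0444), were higher, calls that were lost in 7 and 11 of the 12 fits with 1 library left out. Skeletal muscle genes, high in the females 1 to 4, had a median of 4.43 with no member past the threshold over all genes (18 of 20 rose adjusted over the list alone), and adjusted p = 0.454 with an estimated correlation. Without mice 1 to 4 the count of genes was 9. Of the 35 lists 17 passed the sex effect with the preset correlation, and the Y-linked and X-linked lists were the 2 that passed with an estimated one.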

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

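The comparison with interneuron genes below was among the tests chosen only after the result was seen, as were the term for mice 9 to 12 and the fit without mice 1 to 4 as settings.

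Single mice stood apart from the other 5 of their genotype in 25 of 218 groups of 6, where chance alone gives about 1 in 20, or 10.9. WT female 1 held 9 of these values, P278KY male 7 held 6 and P278KY female 9 held 3. In WT female 1, the mouse with the most muscle RNA, the mean log2 CPM was low for motor neuron genes (4.93, others 5.21 to 5.34) and astrocyte genes (8.11, others 8.24 to 8.27). It was high for reactive astrocyte genes (4.77, others 3.93 to 4.23), ependymal genes (1.98, others 1.36 to 1.57), immediate early genes (3.13, others 2.69 to 2.80) and p53 targets (3.91, others 3.71 to 3.78). The same mouse was low in Nefl (1617 CPM, others 2121 to 2328), Gria4 (169, others 190 to 199) and Gfra1 (83.2, others 94.4 to 101).

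P278KY male 7 was high in sensory ganglion genes (mean log2 CPM 2.81, others 0.18 to 0.42) and in motor neuron genes (4.69, others 4.52 to 4.58). It was also high in P2rx3 (12.8 CPM, others 5.35 to 7.19), Calca (16.9, others 4.6 to 7.1), Gfra1 (84.3, others 79.4 to 81.1) and Gm15710 (0.804, others 0). P278KY female 9, of the set of mice 9 to 12, was low in glucocorticoid-responsive genes (4.87, others 5.34 to 5.52) and clock genes (5.49, others 5.64 to 5.67) and high in Hsp90b1 (347 CPM, others 308 to 319).

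Of the remaining mice, P278KY male 6 had the deepest library (39.3 M expected counts, others 28.8 to 31). P278KY female 3 was high in eIF2 kinases and factors (mean log2 CPM 5.63, others 5.55 to 5.58). In CPM, P278KY female 4 was high in Cass4 (2.12, others 1.69 to 1.82), P278KY male 8 in Gria2 (210, others 188 to 196) and WT male 5 in Gabrr2 (1.14, others 0.49 to 0.732). WT male 12 was high in Sptbn5 (32.2 CPM, others 20.7 to 21.5) and WT female 10 in Slc7a3 (6.07 CPM, others 5.32 to 5.56).

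The genotype effect of 16 lists differed between the sexes by the interaction term with the preset correlation. None of them did with an estimated one, at an adjusted p of 0.605 or higher. The median differences (females minus males, log2) were -2.0 for sensory ganglion, -0.54 for fibroblast and meningeal, -0.50 for ependymal, -0.44 for activated microglia and -0.36 for interferon genes. They were -0.27 for immediate early, -0.24 for reactive astrocyte, -0.20 for glucocorticoid-responsive and -0.09 for axon injury genes. Positive differences were 0.16 for oligodendrocyte myelin, 0.12 for motor neuron, 0.12 for mitochondrially encoded, 0.11 for cholesterol synthesis, 0.10 for astrocyte, 0.05 for nuclear oxidative phosphorylation and 0.03 for ribosomal protein genes. Single mice carry some of these values. Ganglion genes were high in P278KY male 7, WT female 10 and WT male 11 (2.81, 2.28 and 1.99, others 0.12 to 0.42). WT female 1 was the highest of the 12 mice for fibroblast and meningeal (5.36), ependymal (1.98), activated microglia (4.0), reactive astrocyte (4.77) and interferon genes (3.19).

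The motor neuron list had a median of -0.57 in P278KY over WT cord. With a term for mice 9 to 12 the median was -0.54 and without mice 1 to 4, which hold the most muscle RNA, it was -0.66, so neither set of mice accounts for the fall. Interneuron genes had a median of 0.08, which argues against fewer neurons of every kind. A lower expression in motor neurons and a loss of motor neurons both remain open as hypotheses, and the data do not separate them. The list did not pass with an estimated correlation (adjusted p = 0.0605).

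The glucocorticoid list had a positive median in P278KY over WT mice, and the set of mice 9 to 12 holds 3 WT mice and 1 mutant. With a term for these mice the median was 0.22 against 0.35 without it, and that of the clock genes was 0.07 against 0.11. The glucocorticoid value lies between those that the set alone and the genotype alone would give. With the term that list still passed at the preset correlation, and without the term it did not pass with an estimated one (camera adjusted p = 0.297). Among mice 1 to 8 every mutant (mean log2 CPM 5.34 to 5.52) lay above every WT mouse (4.97 to 5.10). This order within mice 1 to 8 argues against the set as the only source, while the median with the term does not decide it. In mice 9 to 12 the 1 mutant (4.87) lay within the WT range (4.79 to 4.97). The clock median decides nothing, since the set was formed from the clock genes. Clock means were 5.64 to 5.67 in mutants and 5.55 to 5.61 in WT mice among mice 1 to 8. They were 5.49 and 5.37 to 5.45 in mice 9 to 12. The labels give no collection times, so time of day or handling and genotype cannot be told apart within a set.

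Other splits of the 12 mice into groups of the same sizes were fitted in the same way. In the other splits the real effect is part of the spread, which can lower their counts. For the genotype effect, 1 of 100 splits, the real one, gave as many genes (956, highest other 23), the smallest share that 100 splits can give. For the sex effect, 2 of 100 splits gave as many (16, highest other 24, with mice 1, 2, 3, 5, 6 and 7 as the female group). That share is under 0.05, though another grouping called more genes than the real one. That grouping had all of mice 9 to 12, low in clock genes, in its other group. Whether this raised its count was not tested. All 4 Y-linked and all 6 X-linked escape genes passed for sex, which argues against chance for those genes. For the other called genes the count alone does not exclude chance. Within females (103, highest other 2) and within males (279, highest other 2), 1 of 10 splits gave as many, and 10 splits are too few for a share under 0.05. For the interaction, where edgeR called 0 genes (665 at an unadjusted p under 0.05, 61 by DESeq2 and 2 by limma voom), 100 of 100 splits gave as many, which a count of 0 fixes in advance, so the splits say nothing about chance here. The highest other split called 852 genes, which points to a structure of the samples: it joined mutant females with WT males, so its interaction is the genotype effect itself. For the fixed lists with the preset correlation, 59 of 100 splits gave as many as the real 12 (highest other 21), and chance cannot be excluded. With an estimated correlation the real split gave 1 list, and 1 of the 99 other splits also gave 1.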

How the results depend on the processing

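The term for mice 9 to 12 and the fits without mice 1 to 4, of mice 1 to 8 only and without mice 7, 10 and 11 were tests chosen after the data had been seen. No paired analysis was possible because no mouse number is shared between groups. Libraries held 26982140 to 39339999 expected counts, and the effect of depth on the calls was not tested. On simulated counts 66.0% of 2-fold changes were recovered in females, 68.0% in males and 72.0% over both sexes.

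The genotype count of 956 was 1617 by DESeq2 (948 shared), 1467 by limma voom (946 shared) and 1654 on log2(TPM + 1) values (615 shared). It was 704 with the term for mice 9 to 12 (628 shared), 557 without mice 1 to 4 (440 shared), 253 without mice 7, 10 and 11 (228 shared) and 84 with mice 1 to 8 only (73 shared). A fold change of at least 1.5 left 132, by its construction. With 1 mouse left out the count ranged from 542 without P278KY male 6 to 1385 without WT female 1. All shared genes kept their sign. Other filters, size factors, unrounded counts and other models gave 775 to 1046.

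The count in females, 103, was 455 by DESeq2, 174 by limma voom, 68 with females only, 52 at a fold change of at least 1.5 and 32 (without P278KY female 4) to 156 (without WT female 1) with 1 mouse left out. The count in males, 279, was 728, 602, 72 with the term for mice 9 to 12, 83 at that fold change and 76 (without WT male 11) to 431 (without WT female 1). The interaction count, 0 by edgeR with 665 genes at an unadjusted p under 0.05, was 61 by DESeq2, 2 by limma voom, 1 with no filter, 4 with the stricter filter and 0 to 42 (without P278KY male 7) with 1 mouse left out. The sex count, 16, was 208 by DESeq2, 25 with the term, 9 without mice 1 to 4, 10 at that fold change and 11 to 17 with 1 mouse left out. Fewer mice were fitted wherever mice were left out. For the other moves the cause was not tested.

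The log2 change of Gars was 0.10 to 0.15 with 1 mouse left out, and the call was lost without any 1 of 10 mice. An estimated correlation took the lists called for the genotype effect from 12 to 1, in females from 18 to 1, in males from 11 to 3, for sex from 17 to 2 and for the interaction from 16 to 0, where DESeq2 called 61 genes and limma voom 2. ATF4 targets kept their call under all 18 settings run on the lists. Of 1918 values of the 74 genes named for genotype, 1578 kept their call, 339 lost it and 1 turned: Gm15710 was at 0.55 with mice 1 to 8 only, which leaves out WT males 11 and 12 that carry its reads. Of these genes 22 kept their call in every setting, among them Fgf21, Chodl, Pmp2, Cars and Spp1. Of 180 values of genes named for sex 157 kept their call and 23 lost it. The odds ratio of called genes near Gars was 0.75 to 1.42 over all windows and settings.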

Other observations

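The correlation of neighbouring genes was a test chosen only after the result was seen, and the B cell, bone marrow and lung genes were chosen after their values were seen.

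The mean log2 CPM of 10 B cell genes was 1.55, 1.02, 0.77 and 0.75 in mice 1 to 4, all females with muscle RNA. It was 0.69 and 0.26 in females 9 and 10 and -0.60 to 0.09 in the 6 males. For sex, all 10 had the higher fitted value in females (mean log2 difference 1.22), 1 passed over all genes, Pou2af1, and 10 adjusted over the list alone. The mean of 8 bone marrow myeloid genes was 3.29 to 4.06 in the P278KY mice and 2.23 to 3.82 in the WT mice, and the fitted change was positive for all 8 (median 0.59), with none of 8 past the threshold for genotype over all genes or over the list alone. Both lists were picked for what they showed, so a list test of them is no separate evidence.

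WT female 1 held transcripts of lung and airway. Sftpc was at 371.7 CPM, Scgb1a1 at 308.3, Sftpb at 78.21, Sftpa1 at 72.36, Ager at 70.77, Cyp2f2 at 39.92 and Sftpd at 14.22 CPM. The highest value in the other 11 mice was 0.52, 1.66, 0.173, 0.208, 0.997, 0.416 and 0.0321 CPM in the same order.

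Neighbouring genes varied together between mice of 1 group, and the hypothesis was that haplotypes of the parental strains C57BL/6J and CAST differ between mice. Of 1362258 pairs of autosomal genes 5 to 20 Mb apart, 0.147% had a residual correlation under -0.9. At shuffled positions the mean was 0.0943% and the highest 0.103% (permutation p = 0.00498, the smallest that 200 shuffles give). A correlation over 0.9 was found for 0.227% of the same pairs (shuffled mean 0.119%, highest 0.128%). Of pairs 20 to 60 Mb apart, 0.119% were under -0.9 and 0.155% over 0.9 (shuffled highest 0.1% and 0.128%). Segments of different strain origin may produce such pairs, and no genotypes were available to test this. On chromosome 3, Bdh2 was at 3.67 to 4.95 CPM in the WT females and P278KY males and at 2.46 to 3.10 CPM in the rest. Bdh2 was named for its small interaction P value, and this division only restates that. The division lies between groups, so it gives no evidence on variation between mice of 1 group.

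Pseudogenes with reads in some mice and none in others were compared with their parent genes, under the hypothesis that reads of the parent are assigned to the pseudogene in some mice. The parent was lower where its pseudogene was higher in 14 of 17 pairs (exact sign test p = 0.0127, median slope -0.89), and for 12 of 15 parent genes (exact p = 0.0352). Rpl34 changed by -0.94 CPM per CPM of Rpl34-ps1 (r = -0.98) and Rpl17 by -0.88 per CPM of Rpl17-ps5 (r = -0.96). The 14 negative slopes ran from -7.58 (Rpsa on Rpsa-ps9) to -0.52 (Scp2 on Scp2-ps2), with -1.82 for Got2 on Got2-ps1. Slopes steeper than -1 are not what an exchange of reads with 1 copy alone would give. Rps13-ps1, Rpl27-ps3 and Pgam1-ps2 were the exceptions, with slopes of 0.04, 0.01 and 1.23. Exchange of reads between near-identical copies may produce these values, and a strain variant that shifts the alignment remains open and untested.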
